A study of Mus musculus with 2 samples.

How the data were processed

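H3K27ac was measured by chromatin immunoprecipitation and sequencing in neural tube from pools of mouse embryos at 12.5 days, in 2 biological replicates of 1 group. The analysis started from 4 deposited peak lists: each replicate's own list, a pooled list made from both replicates and their controls, and a replicated list. Per the file headers, the peaks are on mm10. The peak caller, its version, its thresholds, the aligner and the rule behind the replicated list are not given in the sources used here.

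In all 4 lists, the authors give each peak's fold enrichment over control as a linear ratio, and its p and q values as −log10 p and −log10 q, per the file headers' peak format. The position of the summit within the peak is also the authors'. The lowest −log10 p was 2.04 in replicate 1, 2.03 in replicate 2 and 2.00 in the pooled list, so the lists reach far into weak signal: 21.4%, 28.6% and 22.1% of their peaks have a q above 0.05, against 1.43% of the replicated list. Every replicated peak was identical in position and values to a pooled peak. All 16958 pooled peaks with an overlap of at least 50% of either peak in both own lists were in the replicated list, which also held 8237 others.

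The lists hold no read totals. The pileup and background of each peak were recovered by solving (pileup + 1)/(background + 1) for the fold enrichment together with the Poisson tail for the p-value. The pileup came out whole, within 0.01, for 100% of the peaks of both replicate 1 and the replicated list and 99.997% of those of replicate 2 and the pooled list. The background of a list is the 0.1% quantile over its peaks. Pileups of 8 or more underlie each listed peak of the replicates, and 12 or more each pooled peak, so weaker sites are not listed. Intervals cover counting error only.

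Overlap counted a peak as shared when at least 50% of it, or of the other peak, was covered. It was compared with 100 random placements on the same chromosomes outside assembly gaps. Start sites of all transcripts were from GENCODE M21 on GRCm38, for chromosomes 1 to 19, X and Y. A promoter peak lies within 1000 bp of a start site, and a distal peak is any other; remaining peaks were assigned by midpoint to exon, intron or intergenic sequence, in that order. Distal peaks were counted within 100 kb of any of a gene's start sites, so genes with widely spaced start sites had wider windows.

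The 22 gene lists hold 425 entries, of which 424 matched by symbol and 1 by an older symbol, Drgx, now Prrxl1, which is also among the spinal neuron subtype factors. Promoter shares were compared with all other protein-coding genes by Fisher's exact test, two-sided, and mean distal peaks with random lists by a permutation test of 100000 resamples, two-sided. Both were adjusted by Benjamini-Hochberg over the lists at 0.05. Genes are not independent replicates, so these tests compare lists within the tissue. Distal peaks within 12.5 kb were joined, scored by the sum of fold enrichment times width, and counted above the point where the scaled ranked curve has slope 1. For 17 motifs, the 500 bp around distal summits were compared with windows 10 kb to each side that overlap no pooled peak, by Fisher's exact test with the same adjustment.

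Genes were named by a rule. It took from each list up to 4 members with a promoter peak and the most distal peaks, and up to 3 members without one in alphabetical order. It also took the nearest genes of the top 15 joined regions and of the 10 peaks of highest fold enrichment, and the genes with the 10 widest promoter peaks. Of the list members at which the replicates differ, it took the first 5 of each kind. Hoxb3, Hoxb5, Hoxb8 and Hoxa6 were named because they share a promoter peak with a named gene. Gene lists, motifs, tests, the rule and most alternatives were fixed before the data were examined. Those alternatives were other overlap rules, stricter peaks, each replicate's list alone, the pooled list, other promoter and distal windows, other backgrounds and other joining. A stricter replicated list, and the distal count without the Hox lists, were added afterwards.

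The methods were tested on simulated data. The overlap gave the same answer as bedtools for each of 37235 simulated peaks under all 3 rules. All 5 promoter lists and all 5 distal lists planted among 21938 genes were found, with 0 of 12 random lists called in either test. All 3 planted motifs were found with 0 of 14 others called, 100% of 4863 simulated pileups were recovered, and 30 of 30 planted clusters and 0 single peaks were above the tangent point. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1 were used. CpG-rich promoters had an observed over expected CpG ratio of at least 0.6 and at least 50% GC over 1000 bp. Pileup ratios had bootstrap intervals of 2000 resamples for the replicates and 1000 for chromosome X. Gene families were defined by symbol and compared by Fisher's exact test with the same adjustment over 26 families. Peaks on unplaced sequences were left out of the gene and region results.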

Results

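H3K27ac, the acetylated form of lysine 27 on histone H3 that marks active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the neural tube of mouse embryos at 12.5 days of development. The neural tube is the embryonic precursor of the brain and spinal cord. There was 1 group with 2 biological replicates, a pool of 120 embryos (replicate 1) and a pool of 88 embryos (replicate 2), both of mixed sex and of strain B6NCrl. The design therefore holds no contrast between conditions, and the comparisons are between the replicates, and between gene lists or sequence windows within the tissue. All positions are on mm10. Fold enrichment, p and q of each peak are the authors' own values.

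Replicate 1 had 51925 peaks over 19.9 Mb and replicate 2 had 37450 peaks over 13.4 Mb. The list called on both replicates together held 68257 pooled peaks, and the deposited replicated list, which served for genes and regions, kept 25195 of them (36.9%). The median replicated peak was 499 bp wide with a fold enrichment of 3.72, against 240 bp and 3.28 in each replicate's own list. Read totals were not in the peak lists. A background pileup of 2.96 in replicate 1, 2.92 in replicate 2 and 5.71 in the pooled list was recovered from the fold enrichment and p of the peaks.

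The first question was how far the 2 pools of embryos gave the same acetylated regions. The strongest regions were shared and the weakest mostly were not. Of the peaks of replicate 1, 32.4% (Wilson 95% interval 32.0 to 32.8%) were overlapped in replicate 2, and of those of replicate 2, 50.4% (49.9 to 50.9%) were overlapped in replicate 1. Random placements of the same peaks gave means of 0.811% and 1.14%, and at most 0.911% and 1.38% in 100 placements each. In the decile with the highest −log10 p, 98.4% of the peaks of replicate 1 and 99.8% of those of replicate 2 were shared. In the lowest decile the shares were 8.26% and 24.9%. Shared peaks lay at promoters more often than unshared peaks, at 62.5% against 24.2% in replicate 1 and 61.3% against 21.2% in replicate 2. With a fold enrichment of at least 5, the shares rose to 93.2% and 99.5%. Requiring 50% of both peaks lowered them to 21.4% and 29.7%.

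**Figure D1:**
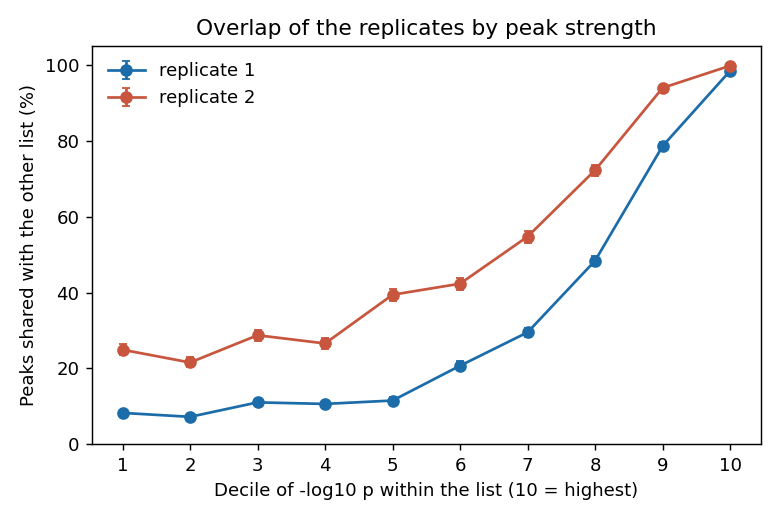
Share of each replicate's peaks (percent, y axis) that were overlapped in the other replicate's list, by decile of −log10 p within the list (x axis), with Wilson 95% intervals as bars. The share goes from 8.26% to 98.4% in replicate 1 and from 24.9% to 99.8% in replicate 2 between the lowest and the highest decile.

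At 17088 replicated peaks overlapped by at least 1 bp in both own lists, the median pileup was 19 in replicate 1 and 15 in replicate 2. The median ratio was 1.25 (interquartile range 1.06 to 1.5), with 77.0% of these peaks higher in replicate 1. The fold enrichments of the replicates had a Spearman correlation of 0.667 across these peaks, which are not independent replicates. Among the members of the gene lists, 45 had a promoter peak only in replicate 1, the first in alphabetical order being Ache, Barhl1, Cdc20, Cdk1 and Chat. Another 17 had one only in replicate 2, beginning with Avil, Bmp7, Bub1, Dlx1 and Fcer1g.

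Acetylated regions lay at gene starts far more often than random placements did. Within 1 kb of an annotated start site of any gene were 51.9% of the replicated peaks (51.2 to 52.5%), against a mean of 8.31% in random placements. Introns held 29.0% (random mean 39.4%), intergenic sequence 16.0% (49.1%) and exons 3.16% (3.18%). Of 21938 protein-coding genes, 9334 (42.5%, interval 41.9 to 43.2%) had a promoter peak. The promoter share of peaks was 32.2% in the pooled list and 82.2% among replicated peaks with a fold enrichment of at least 5, and the latter peaks marked 23.3% of protein-coding genes. Chromosome X held 371 replicated peaks, or 0.391 per protein-coding gene, against 0.854 to 1.67 on the autosomes.

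The top peak, with a fold enrichment of 26.5, spanned the promoter of Kmt5b, a histone H4 lysine 20 methyltransferase (chromosome 19, 3766817 to 3768904). The peak nearest to Chd2, a chromatin remodeller, reached 25.6, but its summit was 16420 bp from the nearest Chd2 start site and lay at a start site of a gene that is not protein-coding. The peak nearest to Setd1b, a histone H3 lysine 4 methyltransferase, reached 24.1 at a summit 3236 bp from its start, while the promoter peak of Setd1b itself had 14.2. That nearest to Mef2c, a transcription factor of neurons and muscle, reached 23.7 at a summit 78079 bp from its start. Both the Mef2c peak and the Setd1b peak of 24.1 lay within 1 kb of an annotated start site of another gene. Ep300, an acetyltransferase that places H3K27ac, had a promoter peak of 23.4. Zc3h4, the actin gene Actb and Ptms had promoter peaks of 23.2, 22.9 and 22.6. An intergenic peak whose nearest gene was Cstad reached 22.8 (chromosome 2, 30691467 to 30694833), and the Hoxb4 peak reached 22.3.

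The widest promoter peaks were at Hox genes, the homeobox genes that set position along the body axis. A single peak of 38924 bp covered the promoters of Hoxb4 and Hoxb3 (chromosome 11, 96308539 to 96347462), against a median of 712 bp for genes with a promoter peak. It was followed by 16960 bp at Hoxb6 and Hoxb5, 12119 bp at Hoxd3, 9440 bp at Hoxb7 and Hoxb8, 9210 bp at Hoxb9, 8010 bp at Hoxa5 and Hoxa6, 7807 bp at Hoxa7 and 7359 bp at Hoxc9. The 2 other genes among the 10 widest were Msi1, an RNA-binding protein of neural progenitors, with 10198 bp, and Meis2, a homeobox cofactor of Hox proteins, with 8448 bp.

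All 15 Hox genes of groups 5 to 9 had a promoter peak (adjusted p = 1.19e-05, Fisher's exact test), as did 10 of 12 in groups 1 to 4 (adjusted p = 0.0135, Fisher's exact test) and 7 of 12 in groups 10 to 13 (adjusted p = 0.494, Fisher's exact test). Hoxb1 and Hoxd1 lacked one, although Hoxb1 had a peak in replicate 1's own list. In the posterior groups fold enrichment was 4.77 at Hoxc10, 4.17 at Hoxc11, 2.68 at Hoxc12 and 4.94 at Hoxd10. Hoxa10 and Hoxd11, named after their values were seen, had the highest posterior values, 8.19 and 6.70. Hoxa13, Hoxb13 and Hoxc13 were among those without a peak. Hoxc12 and Hoxc13 each had a promoter peak in replicate 1's own list but not in replicate 2's. Anterior members reached 22.3 at Hoxb3 and Hoxb4, with 21.2 at Hoxd3 and Hoxd4, 13.6 at Hoxa1 and 12.7 at Hoxc4. Hoxc5, Hoxc6, Hoxc8 and Hoxc9 lay between 9.45 and 11.4. The full range of groups 5 to 9, given after the values were seen, was 6.55 at Hoxd9 to 19.2 at Hoxb9. The 3 lists were compared with all other genes and not with each other. Some neighbouring Hox genes share a promoter peak, as Hoxb3 and Hoxb4 do, which makes these p-values too small. The call for groups 1 to 4 ended when only genes with a replicated peak within 100 kb served as background (adjusted p = 0.161, Fisher's exact test).

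**Figure D2:**
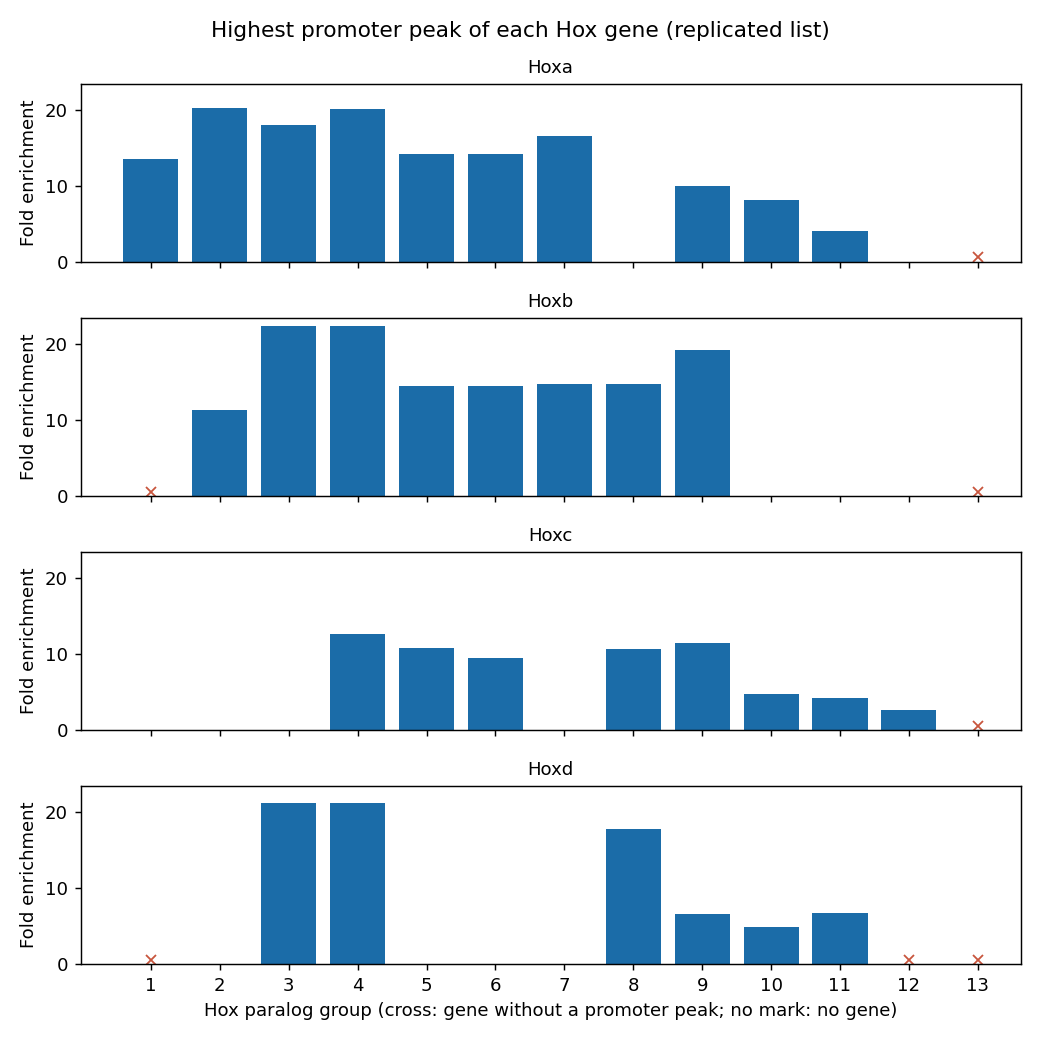
Fold enrichment (y axis) of the highest replicated promoter peak of each Hox gene by paralog group (x axis), with a panel for each cluster; crosses mark genes without a promoter peak. Bars reach 22.3 at Hoxb3 and Hoxb4, and lie between 2.68 and 8.19 in groups 10 to 12 where a peak is present.

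All 25 neural progenitor genes had a promoter peak (adjusted p = 5.69e-09, Fisher's exact test; 42.5% of other genes), among them Notch1, the receptor that holds progenitors undifferentiated, Msi1, Rfx4 and Lfng, a modifier of Notch, with fold enrichments of 7.23, 15.5, 5.81 and 10.3. Of the 30 pan-neuronal genes, 29 had one (adjusted p = 5.69e-09, Fisher's exact test), including Rbfox3, which encodes the neuronal protein NeuN, at 9.02, Ebf3 at 10.7, Myt1l at 9.65 and Nhlh1 at 5.36. Neurod4 was the exception. Both lists also had more distal peaks within 100 kb than random lists, whose mean was 1.52: 5.16 per neural progenitor gene (adjusted p = 0.00224, permutation test; 22 of 25 members above the median of all genes) and 7.43 per pan-neuronal gene (adjusted p = 5.5e-05, permutation test; 26 of 30 members). The median of all genes was 0, so members above it, here and in the lists below, were those with any distal peak. Of all 21938 protein-coding genes, 12290 had no distal peak. Rbfox3 had 52 distal peaks, Ebf3 27, Notch1 20, Myt1l 19, Nhlh1 16, Msi1 14, Rfx4 12 and Lfng 10. The median member had 3 distal peaks in the neural progenitor list and 3.5 in the pan-neuronal list.

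Lists of single domains or neuron types did not pass the test at promoters. In the ventral list 10 of 21 genes had a promoter peak (adjusted p = 0.73, Fisher's exact test). They included Ptch1 (12.2), Gas1 (11.9), Boc (5.38) and Gli2 (3.87), and Dbx1, Dbx2 and Foxa2 were among those without. In the dorsal list 7 of 20 genes had one (adjusted p = 0.73, Fisher's exact test). Zic1 and Zic4 shared a promoter peak of 12.5, Pax3 had 5.66 and Pax7 had 4.17, while Atoh1, Bmp7 and Gdf7 had none. Mean distal peaks were 2.33 in the ventral list (adjusted p = 0.288, permutation test) and 2.5 in the dorsal list (adjusted p = 0.202, permutation test). Of the spinal neuron subtype factors, 16 of 30 had a promoter peak (adjusted p = 0.37, Fisher's exact test), and the list had 4.30 distal peaks per gene (adjusted p = 0.00365, permutation test; 20 of 30 members above the median of all genes). Pax2 had 17 distal peaks, Lhx5 14, Lhx1 13 and Lbx1 9. Barhl1, Evx1 and Evx2 had no promoter peak. Evx2 had 12 distal peaks but lies within 100 kb of Hoxd10, which also had 12, so these genes can share distal peaks. In replicate 1's list 76.7% of these factors had one (adjusted p = 0.00368, Fisher's exact test).

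Of 16 genes of neurotransmitter identity 7 had a promoter peak (adjusted p = 1, Fisher's exact test), with 2.81 distal peaks per gene (adjusted p = 0.149, permutation test). In replicate 1's own list the distal mean was 8.12 and passed (adjusted p = 0.0443, permutation test). Slc32a1, the vesicular transporter of inhibitory neurons, had 4.62, Slc6a5, the glycine transporter, 4.14, Slc17a6, the glutamate transporter, 5.01 and Ddc 3.87, while Chat, Nos1 and Slc17a7 had none. Of 12 gliogenic factors 8 had one (adjusted p = 0.239, Fisher's exact test), and the list had 6.58 distal peaks per gene (adjusted p = 0.00365, permutation test; 11 of 12 members), with 17 at Nfix, 11 at Nfia, 10 at Sox9 and 8 at Fgfr3. In replicate 1's own list 91.7% of these factors had a promoter peak (adjusted p = 0.00458, Fisher's exact test). Cspg4, Slc1a3 and Sox8 had no promoter peak in the replicated list, although Cspg4 had one in both own lists and Slc1a3 and Sox8 in replicate 1's. Of 14 genes of late glia only Slc1a2, a glutamate transporter, had one (7.14%, adjusted p = 0.0135, Fisher's exact test), and Aldh1l1, Aqp4 and Cnp were among the 13 without. In the pooled list the late glia share was 35.7% (adjusted p = 0.378, Fisher's exact test). Mean distal peaks were 1.14 (adjusted p = 0.752, permutation test).

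Forebrain and midbrain factors had no promoter peak in any of 24 genes, Arx, Dlx1 and Dlx2 among them (adjusted p = 1.19e-05, Fisher's exact test; upper bound of the interval 13.8%), and 0.583 distal peaks per gene (adjusted p = 0.192, permutation test). In the replicates' own lists 1 and 3 of the 24 had a promoter peak, Dlx1 in replicate 2 among them, and in the pooled list the share was 29.2% (adjusted p = 0.0484, Fisher's exact test). Lists of tissues outside the nervous system also had few. A promoter peak was found at 1 of 22 genes of blood and microglia (Tal1; adjusted p = 0.000425), 1 of 18 of liver (Apoh; adjusted p = 0.0036), 1 of 16 of heart (Ryr2; adjusted p = 0.0101) and 2 of 18 of the germ line (Gdf9 and Dazl; adjusted p = 0.0143), all by Fisher's exact test. Of these, Ryr2 had a promoter peak only in replicate 2's own list, and Gdf9 and Dazl only in replicate 1's. Aif1, Alas2 and Cd14, Afp, Ahsg and Alb, Actc1, Gata4 and Hand1, and Acrv1, Bmp15 and Ddx4 were among the members without. The liver and heart calls ended at a fold enrichment of at least 5 (adjusted p = 0.165 and 0.0644, Fisher's exact test), and that of the germ line with a promoter window of 2.5 kb (adjusted p = 0.059, Fisher's exact test). Their mean distal peaks, 1.36, 0.333, 1.81 and 1.00, did not differ from random lists (adjusted p = 0.868, 0.154, 0.77 and 0.601, permutation test). The promoter tests of the lists were not matched on CpG-rich promoters. Per autosome, 70.1 to 80.4% of genes with such promoters had a peak, against 35.5 to 53.0% of all genes. Promoter class was therefore not separated from tissue in any list.

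In the lists of tissues next to the neural tube, promoter shares did not pass the test. A promoter peak was present at 10 of 19 genes of neural crest and sensory ganglia (adjusted p = 0.595, Fisher's exact test), including Tfap2a (10.7), Foxd3 (3.69), Mpz (2.75) and Sox10 (2.53) but not Avil, Erbb3 or Hand2. It was present at 6 of 22 genes of somite, muscle and skeletal mesoderm (adjusted p = 0.307, Fisher's exact test), with Foxc1 at 6.26, Col2a1 at 5.20, Foxc2 at 3.58 and Tbx6 at 3.57, and not at Acan, Col1a1 or Col1a2. Of 16 genes of endothelium and pericytes 3 had one (adjusted p = 0.137, Fisher's exact test), namely Egfl7 (3.43), Fli1 (3.16) and Esam (2.53), and Cdh5, Cldn5 and Emcn did not. Mpz, Tbx6, Egfl7 and Esam had a promoter peak in replicate 1's own list but not in replicate 2's. In replicate 2's own list the endothelial share was 12.5% and passed (adjusted p = 0.0368, Fisher's exact test). Mean distal peaks were 1.89, 1.59 and 2.12 (adjusted p = 0.704, 0.942 and 0.551, permutation test).

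Housekeeping genes had a promoter peak at 25 of 27 members (adjusted p = 4.66e-07, Fisher's exact test), with Actb at 22.9, Eef1a1 at 13.4, Ubc at 7.68 and Gapdh at 6.14; Gpi1 and Sdha lacked one in the replicated list, although Gpi1 had one in replicate 1's own list and Sdha in both own lists. Their 2.04 distal peaks per gene did not differ from random lists (adjusted p = 0.546, permutation test). Cell cycle genes had 11 of 20 (adjusted p = 0.37, Fisher's exact test), including Aurka at 4.62, E2f1 at 4.05, Ccnd1 at 3.98 and Mcm2 at 3.72, and none at Ccnb1, Ccnd2 or Cdc20. Their share turned to below other genes in replicate 2's own list (40%, adjusted p = 1, Fisher's exact test) and at a fold enrichment of at least 5 (0%, adjusted p = 0.0195, Fisher's exact test), where it passed. Their 3.50 distal peaks per gene passed the test (adjusted p = 0.0349, permutation test; 10 of 20 members), but not in replicate 1's own list (adjusted p = 0.114, permutation test) or replicate 2's (adjusted p = 0.0597, permutation test). Top2a with 20, Cdc6 with 18 and Mcm2 with 15 held most of these peaks, and the median member had 0.5. Top2a and Cdc6, named after their values were seen, lie within 100 kb of Rara and share distal peaks with it. The retinoic acid pathway had 7 of 16 (adjusted p = 1, Fisher's exact test), with Rara, a retinoic acid receptor, at 9.83, Crabp2 at 4.51, Stra6 at 3.37 and Dhrs3 at 3.28, and none at Aldh1a1, Aldh1a2 or Aldh1a3, the enzymes that make retinoic acid. Its 3.88 distal peaks per gene passed the test (adjusted p = 0.0329, permutation test; 10 of 16 members) and did not with −log10 q of at least 5 (adjusted p = 0.0934, permutation test).

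**Figure D3:**
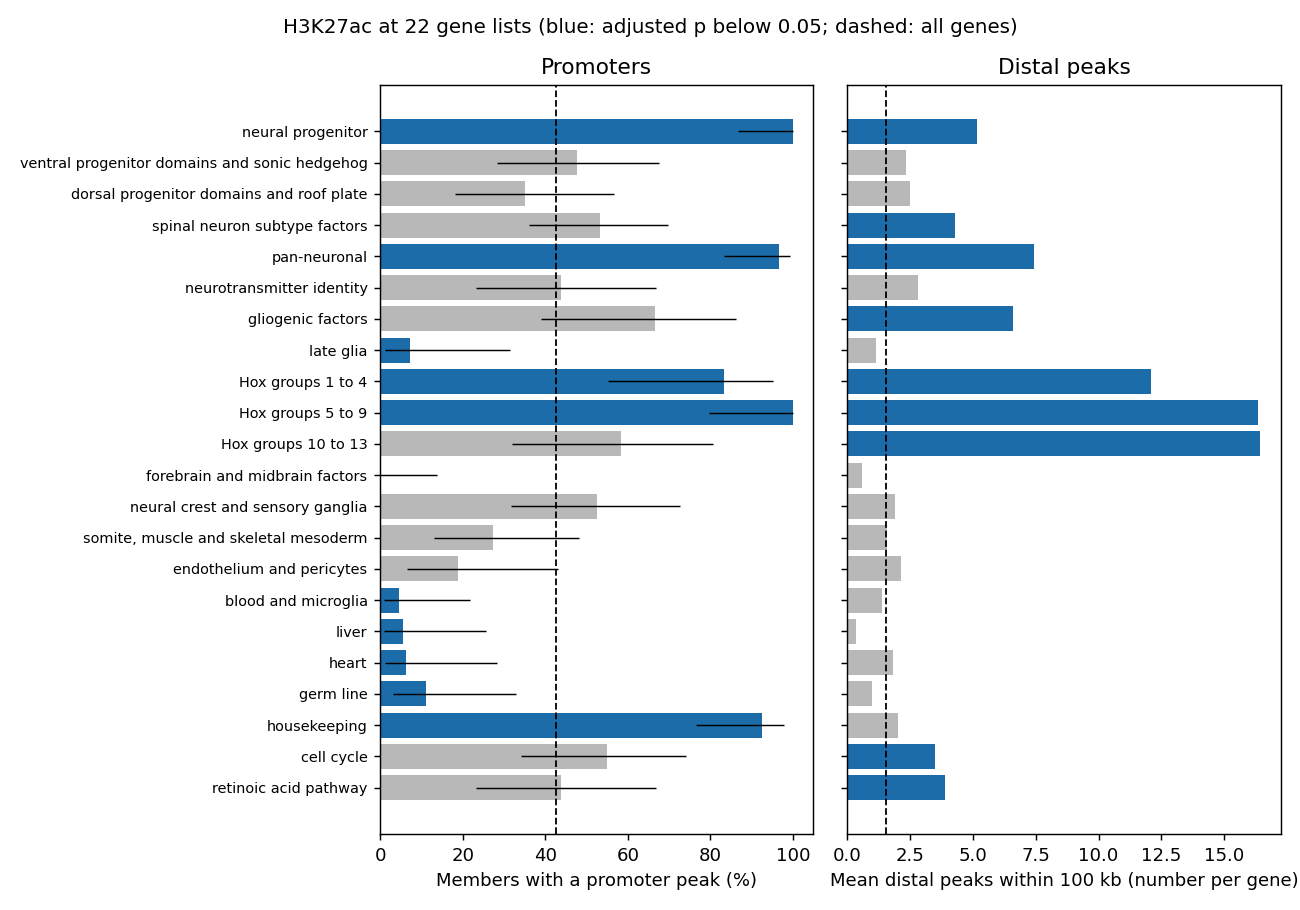
Share of each list's members with a promoter peak (percent, left, with Wilson 95% intervals) and mean number of distal peaks within 100 kb (right) for the 22 gene lists; blue bars passed the test and dashed lines mark all protein-coding genes. Promoter shares of 5 lists lay above and of 6 below those of other genes, and 9 lists had more distal peaks.

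In all, 11 of 22 lists differed from other genes at promoters and 9 in distal peaks. The Hox lists had 12.1, 16.3 and 16.4 distal peaks per gene from the anterior to the posterior list (each adjusted p = 5.5e-05, permutation test, where 1e-05 is the smallest raw p the resamples can give). Hox genes lie side by side and share distal peaks, which makes these p-values too small: with each distal peak given only to its nearest gene, the means were 2.58, 1.13 and 1.5, against 0.553 for all genes, and none passed (adjusted p = 0.0546, 0.236 and 0.156, permutation test). The cell cycle and retinoic acid lists also lost their calls then, with means of 0.9 and 2.25 (adjusted p = 0.655 and 0.0546, permutation test), which left 4 lists.

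Joined over gaps of up to 12.5 kb, the 12125 distal peaks made 6648 regions, of which 297 (4.47%) lay above the tangent point of the ranked curve and held 2001 of the distal peaks and 35.9% of the summed fold enrichment times width. Of all the regions 4211 were single peaks, and clustering was not compared with random placements. The top region joined 63 peaks (chromosome 8, 120322492 to 120525619) and its nearest gene was Gse1, as for the region ranked 15th. Next came regions nearest to Ncor2, a nuclear receptor corepressor (chromosome 5, 125062666 to 125184050, 44 peaks), 1700001O22Rik (chromosome 2, 30687151 to 30787798, 24 peaks), Rara (chromosome 11, 98922674 to 98975372, 17 peaks) and Hoxc4 (chromosome 15, 103020495 to 103123561, 23 peaks). The others of the top 15 were nearest to Irf2bpl, Zmiz1, Psd2, Tuba1a, an alpha-tubulin of neurons, Cstad, Src, Ccdc85c, Notch1 and Cxxc5. Of the lists, 4 were nearest to such regions more often than other genes: pan-neuronal with 6 of 30 (adjusted p = 2.46e-05), neural progenitor with 5 of 25 (adjusted p = 0.0001), Hox groups 1 to 4 with 3 of 12 (adjusted p = 0.00234) and spinal neuron subtype factors with 3 of 30 (adjusted p = 0.0278), all by Fisher's exact test. The regions join the distal peaks counted above, and all 4 lists had passed the distal test, so this is not separate evidence. The count of regions was 516 in replicate 1's own list and 97 with a fold enrichment of at least 5.

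The proneural E-box CAGCTG, bound by factors such as Ascl1, was in 37.2% of 12122 windows at distal summits and 22.6% of 20950 flanking windows (adjusted p = 9.84e-175, Fisher's exact test). ZIC motifs were in 27.6% against 16.5% (adjusted p = 1.31e-124, Fisher's exact test), SOX motifs in 56.0% against 51.8% (adjusted p = 9.78e-13, Fisher's exact test) and RFX motifs in 11.3% against 9.48% (adjusted p = 2.93e-07, Fisher's exact test). EBF (20.7% against 12.2%), ETS (3.59% against 2.09%), NFI (0.115% against 0.0382%), the neurogenic E-box (37.9% against 36.1%) and TEAD (26.2% against 24.7%) made up the 9 enriched motifs of 17 (adjusted p = 4.67e-91, 3.54e-15, 0.0186, 0.00167 and 0.00391, Fisher's exact test). GATA (7.98% against 10.8%), homeodomain (10.2% against 12%), LHX/ISL composite (0.784% against 1.11%) and AP1 (7.71% against 8.45%) motifs were less frequent in peaks (adjusted p = 3.57e-16, 3.81e-07, 0.00603 and 0.0218, Fisher's exact test). POU, CTCF, HNF1 and MEF2 motifs did not pass (adjusted p = 0.0582, 0.28, 0.156 and 0.523, Fisher's exact test). GATA, HNF1, MEF2 and TEAD had been set beforehand to stand for other tissues. TEAD was enriched nonetheless, also against the flanks matched on GC below. CTCF was enriched in replicate 1's own list (ratio 1.35, adjusted p = 0.00462), replicate 2's (1.41, adjusted p = 0.0116) and the pooled list (1.32, adjusted p = 0.00117), by Fisher's exact test. The NFI call ended in the same lists, with ratios of 1.55, 1.77 and 1.12 (adjusted p = 0.203, 0.137 and 0.698, Fisher's exact test). That of AP1 ended in replicate 1's own list and the pooled list, at 0.993 and 0.981 (adjusted p = 0.812 and 0.36, Fisher's exact test).

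The peak windows had 51.2% GC and the flanks 46.0%. Against 3882 flanking windows matched on GC, the homeodomain ratio turned from 0.844 to 1.52 (adjusted p = 1.33e-10, Fisher's exact test) and the LHX/ISL ratio from 0.708 to 2.34 (adjusted p = 0.00617, Fisher's exact test). The POU ratio was then 1.87 (adjusted p = 1.37e-06, Fisher's exact test) and the CTCF ratio 0.631 (adjusted p = 0.0493, Fisher's exact test). SOX, proneural E-box, RFX, TEAD and ZIC motifs still passed, with ratios of 1.26, 1.33, 1.17, 1.1 and 1.14, as did GATA with 0.86. EBF, ETS, NFI, AP1 and the neurogenic E-box did not (adjusted p = 0.0795, 0.217, 0.173, 0.133 and 0.173, Fisher's exact test). The ratio went from 1.7 to 1.08 for EBF, from 1.72 to 1.14 for ETS, from 3.02 to 4.48 for NFI, from 0.911 to 0.901 for AP1 and from 1.05 to 1.04 for the neurogenic E-box. The matched NFI ratio rests on 0.0258% of 3882 flanks, or 1 window.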

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

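The tests of sequencing depth and of a looser overlap rule were chosen after their results were seen; the other tests of explanations were set before. The replicated list held 6 peaks on unplaced or unlocalized sequences, which the gene and region results do not use, with fold enrichments of 1.81 to 16.8. Of the pooled peaks, 23269 (34.1%) were overlapped by at least 50% of either peak in neither replicate's own list. Their median fold enrichment was 2.47 against 2.72 for all pooled peaks, 43.0% had a q above 0.05, and 819 of them were in the replicated list. Both sets were singled out because their numbers exceeded the 3 that a count of 0 allows, which does not show that the peaks are signal. The main gene and region results leave both sets out, except for those 819 pooled peaks.

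Chromosome X had fewer replicated peaks per protein-coding gene than every autosome. Fewer CpG-rich promoters do not account for this alone: among genes with such promoters, 56.1% on X had a promoter peak (Wilson 95% interval 49.7 to 62.4%), below the lowest autosome at 70.1%. The 75th percentile of pileup above background at these promoters was 0.598 of that on the autosomes (bootstrap 95% interval 0.515 to 0.651, 228 genes on X). That interval excludes the 0.7 to 0.85 set for copy number alone in a pool of both sexes, and the ratio lies in the range set for acetylation on 1 active X per cell, 0.4 to 0.65, although the upper bound of its interval is just past that range. A candidate explanation is therefore acetylation of 1 active X, as a hypothesis; differences in mappability or in the kinds of genes on X were not tested.

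Replicate 1 listed more peaks and higher pileups than replicate 2. Deeper sequencing alone does not account for this, since the recovered background differed by a ratio of 1.01, or 1.08 when divided by the smallest peak width of each list (160 and 170 bp), against a pileup ratio of 1.25 at matched peaks. Weaker enrichment over the whole library of replicate 2 may account for it, as the housekeeping promoters also had a median pileup ratio of 1.23 (bootstrap 95% interval 1.17 to 1.55; 22 of 24 genes higher in replicate 1). Measured in the same way at promoters of all 8531 genes marked in both own lists, the median ratio was 1.32, within that interval. A different cell composition of the pools cannot be told apart from weaker enrichment. The ratio at neural promoters was 1.13 times that at housekeeping promoters, with an interval of 0.885 to 1.23 (p = 0.146, permutation test, 70 against 24 genes).

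A set of 8237 replicated peaks was not in both replicates' own lists. A looser overlap rule for both own lists is excluded, because 8107 replicated peaks lacked even 1 bp of overlap in 1 or both of them. Of the 8237, 5722 were in replicate 1's list alone, 1696 in replicate 2's alone and 819 in neither. A second criterion on pooled reads that favours stronger peaks may have kept them: such a peak had a higher −log10 p than one left out with a chance of 0.835. No biological explanation of this set was tested.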

How the results depend on the processing

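Alternatives were set before the data were examined, except the stricter replicated list (pooled peaks in both own lists) and the distal count without the Hox lists, which were chosen after seeing the data. The causes of the changes were not tested unless the setting itself gives them. Overlap shares of replicate 1 and 2 were 36.6% and 55.8% with any overlap of 1 bp, 21.4% and 29.7% with 50% of both peaks, 93.2% and 99.5% at a fold of at least 5, 85.5% and 97.9% at −log10 q of at least 5, and 41.6% and 47.2% with the same number of peaks per list. Replicated peaks numbered 9424 under 50% of both peaks, 6560 at a fold of at least 5 and 15123 at −log10 q of at least 5. The promoter share was 36.6 to 41.4% with either replicate alone, 32.2% in the pooled list, 82.2% at a fold of at least 5, 64.9% at −log10 q of at least 5, 60.5% in the stricter list, 48.1% and 58.8% with windows of 500 bp and 2.5 kb, and 43.5% with 1 start site per gene. The share of genes with a promoter peak was 42.1 to 48.1% with either replicate alone, then 52.6%, 23.3%, 36.5%, 37.1%, 41.9%, 44.0% and 39.1% in the same order of settings. Joined regions above the tangent point numbered 375 to 516 with either replicate alone, 499 in the pooled list, 97 and 142 under the fold and q filters, and 461 at 5 kb. Lists passing in distal peaks were 4 with the nearest gene only, and otherwise 6 to 10; without the Hox lists they were 6. Lists passing at promoters were 9 to 13. Enriched motifs were 5 in the central 200 bp, and otherwise 6 to 10.

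Of 220 promoter shares of lists under alternatives, 189 kept direction and side of the threshold, 6 lost the call, 7 gained it and 18 turned direction; of 264 distal means these were 233, 14, 2 and 15, and of 135 motif ratios 94, 21, 6 and 14. Rare motifs absent from the flanks gave no ratio. Of the turned values, 4 passed the test: cell cycle promoters at a fold of at least 5 (0%), and, with flanks matched on GC, homeodomain (1.52), LHX/ISL (2.34) and CTCF (0.631) ratios. The rest passed in neither setting. At promoters they were cell cycle (40% without replicate 1, 25% in the stricter list), ventral (57.1% without replicate 1 and, turned, 47.6% without replicate 2; 33.3% by q), dorsal (65% pooled), neurotransmitter (12.5% by fold, 31.2% with 1 start site, 53.8% against genes with a peak within 100 kb), Hox groups 10 to 13 (16.7% by fold), neural crest (5.26% by fold, 31.6% by q and with 1 start site, 36.8% in the stricter list, 55.6% against genes with a peak within 100 kb) and retinoic acid (18.8% by fold and with 1 start site, 31.2% by q). Distal means were somite 3.77 without replicate 1 and, turned, 3.82 without replicate 2, 5.36 pooled, 0.0909 by fold, 0.409 by q, 0.682 in the stricter list, 1.14 at 2.5 kb and 0.727 at 50 kb; dorsal 0.15 by fold; neural crest 0.842 and heart 0.812 in the stricter list; blood 1.73 at 500 bp and 1.86 with 1 start site; endothelium 0.688 at 50 kb; late glia 0.643 and heart 0.25 with the nearest gene. Motif ratios were HNF1 0.564 without replicate 1 and, turned, 1.07 without replicate 2, 1.21 in the stricter list and 1.60 with matched GC; POU 0.964 by fold and 0.784 in 200 bp; MEF2 1.5 by fold, 1.03 by q, 1.07 in the stricter list and 1.02 with matched GC; CTCF 0.986 in the stricter list and 0.718 in 200 bp. With 2 replicates and no read totals, absence of a listed peak means only that none reached the threshold at this depth.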

Other observations

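All tests in this part were chosen after the main results were seen. Gene families defined by symbol showed which promoters carry acetylation beyond the lists. The family tests were not matched on CpG-rich promoters. Per autosome, 70.1 to 80.4% of genes with such promoters had a peak, so promoter class was not separated from family. All 7 Meis and Pbx genes, which encode homeobox cofactors of Hox proteins, had a promoter peak (adjusted p = 0.00546, Fisher's exact test), with fold enrichments of 19.4 at Pbx3, 15.9 at Meis1, 13 at Meis2 and 12.5 at Pbx1, and a mean of 7.29 distal peaks within 100 kb. Of 21 genes with a Kmt, Setd, Nsd or Ezh symbol 20 had one (adjusted p = 1.35e-06, Fisher's exact test), all but Ezh1, with 26.5 at Kmt5b, 19.8 at Kmt2e, 17.9 at Setd5 and 14.2 at Ezh2. These symbols include histone lysine methyltransferases but do not define that class. Of 22 Eph receptors and ephrins, which guide axons, 18 had one (adjusted p = 0.000665, Fisher's exact test), with 11.1 at Ephb2, 9.83 at Efna3 and 8.19 at Epha7, and not at Epha1, Epha6, Epha8 or Ephb1. Plexins (7 of 9, adjusted p = 0.0654), Robo and Slit genes (6 of 7, adjusted p = 0.0679), semaphorins (11 of 20, adjusted p = 0.332) and Sox genes (13 of 19, adjusted p = 0.0552) did not pass, all by Fisher's exact test.

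Cytosolic ribosomal proteins (71 of 79, adjusted p = 1.22e-17), Zfp genes (221 of 365, adjusted p = 1.84e-11) and proteasome subunits (25 of 39, adjusted p = 0.0162) were also above other genes, all by Fisher's exact test. No promoter peak was found at 1093 olfactory receptor genes (upper bound of the Wilson 95% interval 0.35%) or 42 beta-defensins, and 1 was found at 327 vomeronasal receptors. Wnt genes (3 of 19, adjusted p = 0.0336), Nkx genes (1 of 14, adjusted p = 0.012) and potassium channels (18 of 94, adjusted p = 7.09e-06) were below other genes, all by Fisher's exact test, with Wnt4, Wnt5a and Wnt7b marked. Among 57 clustered protocadherins 3 had a promoter peak (adjusted p = 1.25e-09, Fisher's exact test), namely Pcdhac2, Pcdhgc3 and Pcdhgc4. Of 7798 long noncoding genes that start more than 2000 bp from a protein-coding start, 556 (7.13%, Wilson 95% interval 6.58 to 7.72%) had a peak at their start. Of the 2357 nearer to a protein-coding start, 1151 (48.8%) had one.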
